A study of Homo sapiens with 6 samples.

How the data were processed

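RNA from 6 libraries of MDA-MB-231, a human triple-negative breast cancer cell line, was measured by RNA sequencing. The labels place the libraries in 3 groups of 2: parental cells, a derivative resistant to everolimus and kept in 20 µM of it, and a derivative resistant to ridaforolimus and kept in 30 µM of it. Both drugs are analogs of rapamycin, which binds the immunophilin FKBP12 and inhibits the mTOR kinase. One label field gives the parental libraries DMSO as their treatment, while the protocol gives them no drug. Per the labels' protocols, the kit was Illumina's TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand.

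The authors deposited raw read counts per Ensembl gene, 1 column per library, with no normalisation and no pooling. Trim Galore 0.6.6, STAR 2.7.9a, HTSeq 0.13.5 and DESeq2 are named, without their roles, per the submitters' processing notes, with the genome build GRCh38 (hg38). The strand setting of the counting and the annotation release are not given in the sources used here. Counts of overlapping and antisense genes are therefore uncertain, as are those of near-identical copies such as HLA genes, the AKR1C family and histone genes, whose reads the counting could drop or share. The table held 69292 gene IDs, of which 28459 had no count in any library. A symbol table matched 62625 IDs. The 6667 without a match took 0.00288% to 0.00399% of the counts. GENCODE 29, an annotation of GRCh38, gave positions and gene types for 58279 IDs. Positions printed here come from it and may differ slightly from those of the authors' annotation.

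Total counts per library were 13512908 and 14524155 in the parental group, 13141320 and 15556246 in the everolimus group and 13134567 and 13451139 in the ridaforolimus group. Between 32356 and 33463 genes had a count in each library. Floors and intervals of counts cover counting error only, not the spread between libraries. No molecular identifiers are stated, so duplicate reads may make even the counting error larger than these limits assume. A group in which a gene had 0 counts was given a floor of 3 counts over the group's libraries together.

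Changes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr by group, glmQLFit and glmQLFTest on a model with the 3 groups, fitted to all 6 libraries with 3 residual degrees of freedom. Tests were two-sided, and the Benjamini-Hochberg adjusted p had to be under 0.05 over the 21223 genes tested. Adjusted p-values in the text come from this test unless another tool is named. Fold changes are log2 values of the first group over the second, given ± the standard error, and intervals are 95% intervals from the same fit. CPM are counts relative to the TMM-scaled library size, given as mean ± SD over the 2 libraries of a group. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as other tools on the same genes. DESeq2 left 3704, 2058 and 1235 genes without an adjusted p in the everolimus, ridaforolimus and direct comparisons.

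For gene groups, 51 lists of pathway genes and cell type markers were fixed before the data were examined, as were the design, most other settings tried and the rule for named genes. Of them, 49 had at least 5 tested genes. Each was tested against all other genes with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 49 lists of a comparison. The test was repeated with a correlation estimated from the data and with fry, which called 0 lists in every comparison. No list call held with an estimated correlation. The lowest adjusted p of any list was then 0.389 in the everolimus, 0.919 in the ridaforolimus and 0.890 in the direct comparison. The sign of the median, the mean and the test was the same for every called list.

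Genes were named by this rule: PMEPA1 and any component of TGF-beta or PI3K/AKT/mTOR signalling; per comparison the 8 largest rises and 8 largest falls past the threshold at a mean of at least 10 CPM, with groups that do not overlap and a symbol that is not a pseudogene, clone, LINC or antisense name; up to 4 called members of each list at a mean of at least 1 CPM; the largest shared and opposite changes; and drug transporters, FK506-binding proteins and cell type markers by value. Members of a list without called members may be given as values. Members that passed only when adjusted over the list alone, and MYC and PVT1, were singled out after their values were seen.

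Both resistant lines were compared with the same 2 parental libraries, so their fold changes share chance values. Unchanged groups were simulated in 40 rounds, with all 6 libraries drawn anew from the parental means, so that both lines again shared their controls. The chance values of the real parental libraries were not kept in these simulations. The simulated correlation and overlap are given beside the observed ones. The fitting was tested on simulated counts for the 21223 genes, with 200 genes changed in each of 5 rounds. The changed genes were drawn only from those at a mean of at least 1 CPM, so recovery of lower genes was not tested. Each gene was drawn on its own, without spread shared by the genes of a library. In the everolimus comparison edgeR recovered 14.0%, 75.6%, 92.4% and 96.0% of genes changed 2, 4, 8 and 16-fold, and 8.07% of its calls were false. In the ridaforolimus comparison it recovered 10.4%, 76.0%, 93.2% and 96.0%, with 8.74% false calls. DESeq2 had 16.9% and 17.9% false calls in these simulations.

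The replicates were compared before averaging. Log2 CPM of the libraries of a group correlated across genes at 0.983 (parental), 0.970 (everolimus) and 0.972 (ridaforolimus). The everolimus libraries correlated less with each other than replicate 1 did with the parental libraries (0.974 and 0.973) or replicate 2 with parental replicate 2 (0.974; 0.961 with parental replicate 1). Counts within a group differed by more than sampling noise, with a chi-square per gene of 15.8, 39.2 and 36.8. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. No batch or date is given in the labels.

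Other settings chosen in advance were other scaling factors, no filter and a stricter filter on low counts, fits to only the groups compared, a replicate block, leaving out each library, other tools and thresholds, and other settings of the list tests. A cell-cycle covariate, a fit without genes of chromosome X, a fit of protein-coding genes only and a split of the parental libraries between the lines were added after the data had been seen. All columns of the table were used.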

Results

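The study asked which changes in expression go with acquired resistance of breast cancer cells to drugs against mTOR, and its title names PMEPA1, TGF-beta signalling and PI3K/AKT. Gene expression was measured in parental MDA-MB-231 cells, in a derivative grown for months in 20 µM everolimus and in one grown in 30 µM ridaforolimus, with 2 libraries per group. Each resistant line was a single derivative kept in its drug, while parental cells had neither drug. Resistance, exposure to the drug and changes of that derivative in culture therefore cannot be told apart in these comparisons. Depth ranged from 13134567 to 15556246 counts per library. The first principal component, with 36.1% of the variance, set both ridaforolimus libraries (scores 36.4 and 73.2) apart from the other 4 (-33.7 to -22.1).

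PMEPA1, a membrane protein induced by TGF-beta that binds receptor-activated SMADs and dampens the pathway, was higher in both resistant lines than in any parental library. Groups of 2 libraries separate in this way, in either direction, for 33.3% of genes by chance. Of all genes tested 41.1% did so in the everolimus and 49.4% in the ridaforolimus comparison. The level of PMEPA1 was 18.3 ± 7.01 CPM in parental cells, 38.5 ± 12.2 CPM in everolimus-resistant cells and 48.9 ± 1.83 CPM in ridaforolimus-resistant cells (SD, n = 2 each). The log2 fold change was 1.08 ± 0.32 in the everolimus line (95% interval 0.35 to 1.80) and 1.42 ± 0.32 in the ridaforolimus line (0.69 to 2.15). Neither passed the threshold over all genes tested (adjusted p = 0.444 and 0.117, edgeR's quasi-likelihood test), and the lines differed from each other by 0.34 (interval -0.36 to 1.05, adjusted p = 0.672). DESeq2 gave an adjusted p of 0.172 and 0.00633. PMEPA1 (ENSG00000124225) lies on chromosome 20 at 57648392 to 57711536 on the minus strand of GRCh38. The study names this gene and may have chosen it on these samples, so its place in a list of TGF-beta targets is no independent evidence. Without parental replicate 1 the fold changes became 1.53 and 1.87, without parental replicate 2 they were 0.73 and 1.07, and without everolimus replicate 2 the first was 0.70.

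The comparison of everolimus-resistant with parental cells asked how the everolimus line differed from its origin. CASC19, a long non-coding RNA encoded near MYC, fell from 335 ± 73.2 CPM to 14.5 ± 7.68 CPM (SD, n = 2), a log2 fold change of -4.53 ± 0.39 (adjusted p = 0.0473). It was the only gene that passed the threshold. As groups, genes of the amino-acid response driven by ATF4, of epithelial identity, of the mitochondrial genome and of the endoplasmic reticulum chaperones were lower than other genes, and genes of cholesterol synthesis were higher. All of these group calls rest on the preset correlation. CASC19 (ENSG00000254166) lies on chromosome 8 at 127072694 to 127227541, and its neighbours MYC and PVT1 had log2 fold changes of 0.00 and 0.39 that did not pass.

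Among the 34 tested ATF4 targets, 33 estimates were below 0 (median -0.95, adjusted p = 1.99e-07 by camera). The list had adjusted p = 0.984 with an estimated correlation. No member passed, over all genes or adjusted over the list alone. The stress factor DDIT3 stood at -1.40, the cystine transporter SLC7A11 at -1.22 and the glutathione-degrading enzyme CHAC1 at -2.28, while ATF3 stood at 1.00. In single libraries the level of this list was 0.56 and 0.71 in parental, 0.19 and -0.87 in everolimus and 0.55 and -1.23 in ridaforolimus cells, on a log2 scale centred on the 6 libraries. Of 22 epithelial genes 17 were below 0 (median -0.55, adjusted p = 2.04e-07, and adjusted p = 0.389 with an estimated correlation). None passed over all genes, and 10 fell when adjusted over the list alone. They included the adhesion molecule EPCAM (-1.94 ± 0.38), the tight-junction protein CLDN7 (-1.50 ± 0.28), the splicing factor ESRP1 (-1.31 ± 0.29) and the protease inhibitor SPINT1 (-3.61 ± 0.56).

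All 13 mitochondrially encoded mRNAs were below 0 (median -0.70, adjusted p = 3.25e-07, and adjusted p = 0.984 with an estimated correlation), and 4 fell when adjusted over the list alone, led by MT-ND2 (-1.41 ± 0.26). Mitochondrial genes took 4.38% and 3.0% of the counts in parental, 2.38% and 2.15% in everolimus and 2.42% and 3.19% in ridaforolimus libraries. Of 27 ER chaperone genes 26 were below 0 (median -0.35, adjusted p = 1.04e-04, and adjusted p = 0.984 with an estimated correlation), with HSPA5, the main luminal chaperone, at -0.96 and 0 members past the threshold adjusted over the list alone. Of 24 cholesterol synthesis genes 21 were above 0 (median 0.57, adjusted p = 0.0141, and adjusted p = 0.984 with an estimated correlation), with INSIG1 at 2.11 and HMGCS1 at 1.54 and 0 members past the threshold over the list alone. The cholesterol list had an adjusted p of 0.210 without parental replicate 1 and turned to the other direction without everolimus replicate 2 (adjusted p = 0.287).

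In the pathways that the title names, no gene of the everolimus line passed over all genes. The 29 tested TGF-beta ligands, receptors and SMADs had a median of 0.11 (adjusted p = 0.308), and 1 rose when adjusted over the list alone, the inhibitory SMAD7 (1.37 ± 0.29, adjusted p = 0.298 over all genes). TGFB2 stood at 0.82, FST at 1.66, TGFBR1 at 0.17 and TGFBR2 at -0.12. The 28 SMAD target genes had a median of -0.22 (adjusted p = 0.487), with SMAD7 alone past the threshold adjusted over the list alone. Of the 51 components of PI3K/AKT/mTOR signalling none passed over the list alone either (median 0.04, adjusted p = 0.805). MTOR stood at 0.02, AKT1 at -0.03, PIK3R1 at 0.80 and the translation repressor EIF4EBP1 at -1.05. FKBP1A, the gene of the drugs' binding protein FKBP12, stood at 0.00, and its family of 19 immunophilins had 0 members past the threshold adjusted over the list alone (median -0.00, adjusted p = 0.685). The 16 tested ABC drug transporters, ABCC1 among them at 0.09, had 0 as well (median 0.14, adjusted p = 0.961).

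In this comparison 1866 genes, 8.79% of those tested, had an unadjusted p under 0.05, where a share of 0.05 does so with no change. Of them 1 passed the adjusted threshold, and limma-voom called 1 and DESeq2 150 (49 higher, 101 lower). A fit to only these groups and one with a replicate block called 0 genes each. CASC19 lost its call without parental replicate 1 (adjusted p = 0.102), parental replicate 2 (0.216), ridaforolimus replicate 1 (0.0905) or ridaforolimus replicate 2 (0.0935), while 3 genes passed without everolimus replicate 1 and 2 without everolimus replicate 2.

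**Figure D1:**
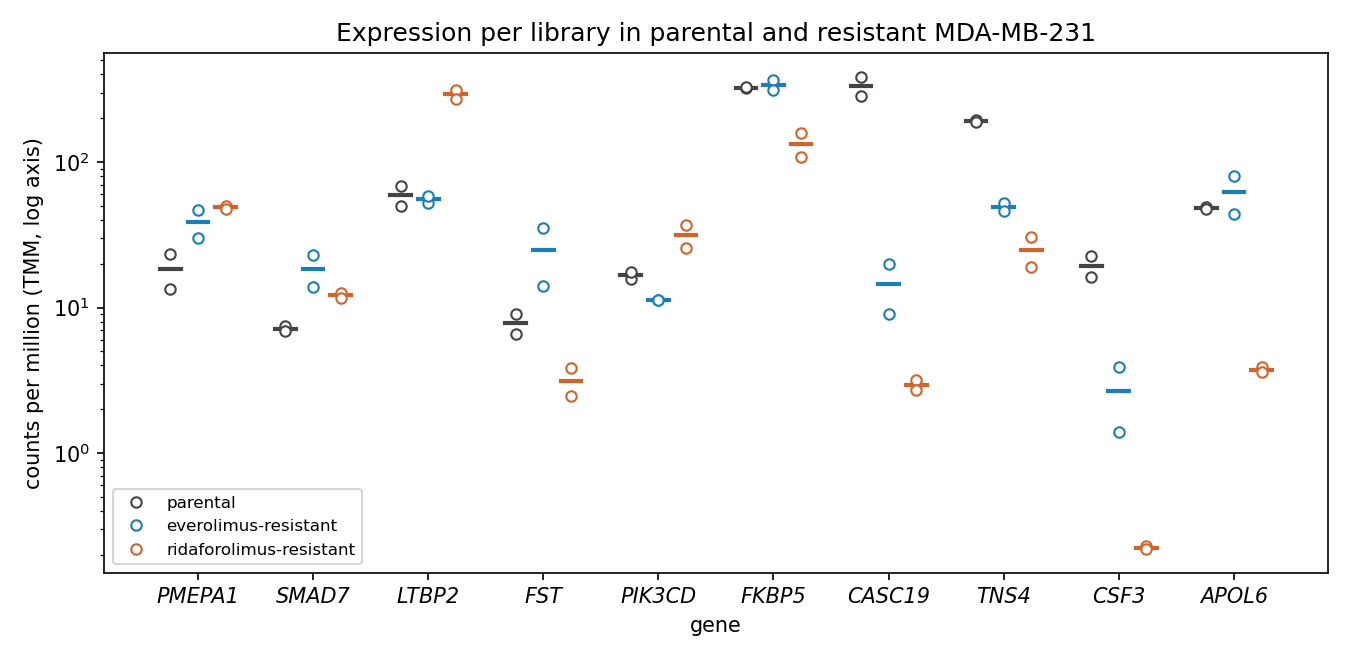
Expression of 10 genes (horizontal axis) in CPM (TMM-scaled, vertical log axis) in parental, everolimus-resistant and ridaforolimus-resistant MDA-MB-231 cells; each circle is 1 library and each bar the mean of the 2 libraries of a group. CASC19 goes from 335 to 14.5 and 2.95 CPM, TNS4 from 191 to 49.0 and 24.8 CPM, and LTBP2 from 59.1 to 55.3 and 293 CPM.

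Ridaforolimus-resistant cells were compared with parental cells in the same way. In them 68 genes passed the threshold, 41 higher and 27 lower, each by at least 2-fold. LTBP2, a fibrillin-binding matrix protein of the latent TGF-beta binding protein family, rose from 59.1 ± 12.9 to 293 ± 31.7 CPM (SD, n = 2), and the cytokine CSF3 fell from 19.4 ± 4.43 to 0.224 ± 0.00671 CPM. The focal adhesion protein TNS4 and the nicotinamide methyltransferase NNMT also fell, and many of the genes that rose lie together on chromosome X. As groups, genes of oxidative phosphorylation, ribosome biogenesis, the ATF4 response, interferon response and mitosis were lower than other genes, and genes of glycolysis were higher. All of these group calls rest on the preset correlation and ended with an estimated one (adjusted p = 0.919 each).

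The largest rises among well expressed genes were EDA, a ligand of the TNF family (4.64 ± 0.45, adjusted p = 0.0109), the nucleosome-binding HMGN5 (3.67 ± 0.45), the focal adhesion protein TNS1 (3.39 ± 0.46), the metalloprotease ADAMTS6 (3.17 ± 0.39) and the adhesion molecule CNTN1 (2.95 ± 0.37). LTBP2 (2.31 ± 0.22), SH3BGRL (2.29 ± 0.23) and the chromodomain protein CDYL2 (2.29 ± 0.25) followed. CASC19 led the falls under the naming rule at -6.82 ± 0.45 (adjusted p = 0.00539), while SPANXB1, a gene of chromosome X outside that rule, stood at -6.92 (adjusted p = 0.011). NNMT stood at -4.06 ± 0.49, the apolipoprotein APOL6 at -3.70 ± 0.32, TNS4 at -2.94 ± 0.26, the Rac activator TIAM1 at -2.72 ± 0.27, the flippase ATP10A at -2.59 ± 0.25, the lipid droplet protein PLIN4 at -2.33 ± 0.29 and MXRA8 at -2.32 ± 0.24. Adjusted p-values of these genes lay between 0.00539 and 0.0290 (edgeR's quasi-likelihood test). CSF3 (-6.38 ± 0.62) was the 1 gene of the NF-kB and cytokine list that changed, the coagulation factor F3 (-1.50 ± 0.19) the 1 of the YAP/TAZ targets and RPS4X (1.51 ± 0.20) the 1 of the cytosolic ribosomal proteins. Of the endothelial marker list TIE1, a receptor of vessel cells, rose from 0.734 to 13.2 CPM on average, while its other 5 tested members did not pass over all genes.

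Of the 40 rises with a position, 22 were on chromosome X, which holds 588 of the 20202 positioned genes tested (2.91%; Fisher's exact test, two-sided, p = 7.6e-24), and 21 of them lay between 60 and 90 Mb. Fisher's test takes genes as independent, but these neighbours moved together, so its p-value overstates the evidence. In the region from 60 to 90 Mb, whose borders were chosen after the values were seen, 96 genes were tested. Of these, 59 had a mean of at least 5 CPM over the 6 libraries. All 59 had a higher estimate in the ridaforolimus line, with a median of 1.37. That mean includes the ridaforolimus libraries, so a gene high only there could pass it, and the other tested genes are not in this count. EDA, HMGN5, SH3BGRL and RPS4X are among the genes there. From 90 Mb to the end 88.8% of 161 genes were lower, with a median of -0.67, and the medians of the everolimus line were 0.02 and -0.06. Without the genes of chromosome X, 37 genes passed.

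**Figure D2:**
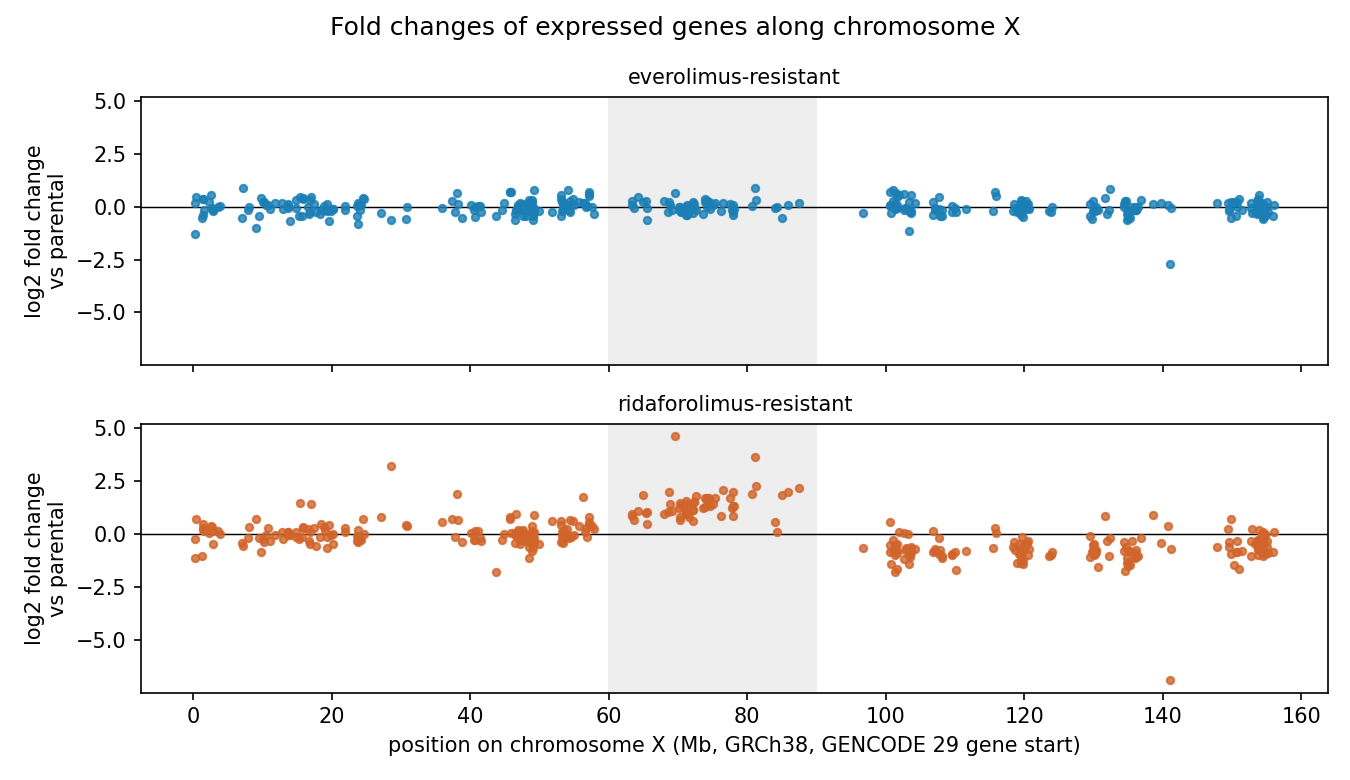
Log2 fold change against parental cells (vertical axis) by gene start on chromosome X in Mb (GRCh38; horizontal axis) in everolimus-resistant (upper) and ridaforolimus-resistant cells (lower); each point is 1 gene at a mean of at least 5 CPM, and grey marks 60 to 90 Mb. In the lower panel the 59 genes of the grey region have a median of 1.37 and the 161 genes beyond it a median of -0.67, against 0.02 and -0.06 in the upper panel.

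Of 73 nuclear genes of oxidative phosphorylation 64 were below 0 (median -0.31, adjusted p = 1.24e-05 by camera, and adjusted p = 0.919 with an estimated correlation, as for each list of this comparison that follows). None passed over all genes, and adjusted over the list alone NDUFB9 (-1.16) and NDUFA1 (-1.22) fell and COX7B (0.87) rose; NDUFA1 lies beyond 90 Mb on chromosome X and COX7B between 60 and 90 Mb. Ribosome biogenesis had 36 of 40 genes below 0 (median -0.35, adjusted p = 2.72e-04), with NOP56 at -0.85 and DKC1, also beyond 90 Mb on X, at -0.93. The ATF4 targets had 31 of 34 below 0 (median -0.49, adjusted p = 2.72e-04), with the serine synthesis enzyme PHGDH at -2.75 and ATF3 at 1.5. The mitotic genes had 33 of 40 below 0 (median -0.37, adjusted p = 0.0143), with MKI67 at -0.66 and CCNB1 at -0.79. ER chaperones had 23 of 27 below 0 (median -0.28, adjusted p = 0.0143), with HYOU1 at -1.07. In these 4 lists 0 genes passed adjusted over the list alone.

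Interferon response genes had 27 of 33 members below 0 (median -0.38, adjusted p = 0.0109), and adjusted over the list alone 3 fell: ISG15 (-1.59), OASL (-1.36) and IFIT2 (-0.99). The list of MHC class I and antigen presentation had 16 of 21 below 0 (median -0.19, adjusted p = 0.0141). The 3 members that fell when adjusted over the list alone, HLA-DRA (-2.57), CD74 (-2.12) and CIITA (-1.62), belong to class II presentation or its control. All 13 mitochondrially encoded mRNAs were below 0 (median -0.46, adjusted p = 0.0122), and 1, MT-ND2 (-1.03), fell when adjusted over the list alone. Glycolysis had 20 of 23 genes above 0 (median 0.37, adjusted p = 0.0169), and PGK1 (1.99), a glycolytic enzyme encoded in the X region above, was the 1 that rose when adjusted over the list alone. NRF2 targets had 19 of 27 above 0 (median 0.28, adjusted p = 0.0344), with AKR1C3 at 2.10, TXNRD1 at 1.02 and 0 past the threshold over the list alone. All of these lists had adjusted p = 0.919 with an estimated correlation.

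Several list calls of the ridaforolimus line rested on 1 library. Without ridaforolimus replicate 2 the adjusted p was 0.560 for ribosome biogenesis, 0.616 for the ATF4 targets, 0.284 for glycolysis and 0.666, with the direction turned, for mitosis, and without ridaforolimus replicate 1 it was 0.152 for interferon response, 0.493 for antigen presentation, 0.161 for mitochondrial mRNAs and 0.272 for NRF2 targets. Without parental replicate 1 it was 0.125 for ER chaperones and 0.352 for mitochondrial mRNAs, and without parental replicate 2 it was 0.236 for glycolysis, 0.423 for mitosis and 0.204 for NRF2 targets. With at least 5 CPM in 2 libraries it was 0.0815 for interferon response, 0.139 for antigen presentation and 0.0521 for ER chaperones. In fits added after the data had been seen, these lists and mitosis had 0.0521 each with protein-coding genes only, mitosis 0.0776 with a cell-cycle covariate and NRF2 targets 0.0722 without genes of chromosome X.

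Among the 28 SMAD target genes LTBP2 rose over all genes, and adjusted over the list alone 3 rose, LTBP2, PMEPA1 (1.42) and the matrix protein TGFBI (1.60), and NEDD9 (-1.93) fell. The list as a whole did not pass (median 0.36, adjusted p = 0.211), nor did the TGF-beta ligands, receptors and SMADs (median 0.19, adjusted p = 0.309; 0 members adjusted over the list alone), with SMAD3 at 0.69, SMAD7 at 0.76, TGFB1 at 0.44, TGFB2 at -0.42, TGFBR1 at -0.09 and TGFBR2 at -0.30. No component of PI3K/AKT/mTOR signalling passed over all genes, and 6 rose when adjusted over the list alone, among them PIK3CD (0.91), PIK3CG (1.88), EIF4B (0.96), the translation inhibitor PDCD4 (0.99) and SESN3 (1.21), a sestrin. This list had a median of -0.01 (adjusted p = 0.891), with MTOR at -0.32, AKT1 at -0.21, RPS6KB1 at -0.56 and EIF4EBP1 at -0.77. FKBP1A stood at 0.04, while among the 19 immunophilins FKBP5 (-1.28) fell and FKBP10 (1.57) rose when adjusted over the list alone (list adjusted p = 0.474). The 16 ABC transporters had 0 such genes (median 0.16, adjusted p = 0.609), with ABCC1 at -0.12 and ABCG2 at 1.00. Of the 22 epithelial genes LAMB3 rose and 6, KRT18, EPCAM and CLDN7 among them, fell when adjusted over the list alone (list adjusted p = 0.111).

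DESeq2 called 574 genes here (291 higher, 283 lower), all 68 of edgeR's among them, and limma-voom 72. The count of 68 became 127 in a fit to only these groups and 28 with a replicate block. It was 1 without parental replicate 1, 1 without parental replicate 2 and 2 without ridaforolimus replicate 2, and was 56 without ridaforolimus replicate 1, 276 without everolimus replicate 1 and 236 without everolimus replicate 2.

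The 2 lines were next compared with each other, since both were selected on rapamycin analogs. Everolimus and ridaforolimus differ at 1 hydroxyl of rapamycin's cyclohexyl side chain, which carries a hydroxyethyl ether in the first and a dimethylphosphinate in the second. Their doses differed (20 and 30 µM), so the responses are not matched for dose. CASC19 fell in both lines, and was lower in the ridaforolimus than in the everolimus line by a further -2.29 ± 0.39 (interval -3.20 to -1.38, adjusted p = 0.0499, a call that 13 of 17 other settings ended). It was the 1 gene that fell past the threshold in both, against 0.00127 for independent lists and 0 in 40 simulations of unchanged lines with shared simulated controls. No gene rose in both (simulated mean 0.075, at most 1), and none passed in opposite directions. The simulated lines held no true change, so few of their genes could pass in either line. These simulated overlaps therefore do not show how often lines that differ would share a call through the same controls. CSF3 (-2.88 and -6.38) and TNS4 (-1.96 and -2.94) were lower in both lines, but in the everolimus line their adjusted p was 0.205 each. The differences between the lines were -3.50 for CSF3 (interval -5.02 to -1.99, adjusted p = 0.0645) and -0.98 for TNS4 (-1.55 to -0.41, adjusted p = 0.135).

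Across all genes the fold changes of the lines correlated at 0.383 (Pearson) and 0.400 (Spearman), where simulated unchanged lines gave 0.501 and 0.469, and genes are not independent replicates. Their covariance was 0.158 against a simulated 0.117, a difference of 0.041. At an unadjusted p under 0.05, 553 genes moved the same way (254 up, 299 down; independent lists 66.4 and 69.0; simulated 227 in all), and 81 moved in opposite ways (simulated 2.33). DESeq2 called 12 genes up and 37 down in both lines, where independent lists give 0.672 and 1.35, and 3 in opposite directions. Part of the excess over independent lists may come from the shared controls. In a split chosen after the data had been seen, which leaves 1 parental library per line and 2 residual degrees of freedom, the covariance was 0.0653 with parental replicate 1 for the everolimus line and 0.103 with replicate 2 for it, and the correlation 0.119 and 0.204. At an unadjusted p under 0.05, 147 and 152 genes then moved the same way (independent lists 35.0 and 24.2) and 71 and 25 in opposite ways, and 0 genes passed in both lines. The 1 shared gene was lost without either parental replicate or either ridaforolimus replicate (0 genes each), and 2 genes were shared without everolimus replicate 1.

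Tested directly, the ridaforolimus line differed from the everolimus line in 158 genes, 100 higher and 58 lower; a fit to only these groups called 0 and a replicate block 49. LTBP2 (2.40 ± 0.22) and the calcium-binding CALB2 (2.72 ± 0.27) were higher in ridaforolimus-resistant cells, as was PIK3CD, the delta catalytic subunit of PI3K (1.47 ± 0.25, adjusted p = 0.0475; 31.3 ± 8.03 against 11.3 ± 0.0530 CPM). Follistatin (FST), which binds activins, was lower (-2.97 ± 0.48, adjusted p = 0.0403), at 24.7 ± 15.1 CPM in the everolimus and 3.15 ± 0.938 CPM in the ridaforolimus line. FKBP5, an immunophilin and co-chaperone, was lower as well (-1.35 ± 0.23, adjusted p = 0.0499; 339 ± 38.7 against 133 ± 35.2 CPM). Of 18 other settings 12 ended the call of PIK3CD, 11 that of FST and 14 that of FKBP5, while LTBP2 and CALB2 lost theirs in 1 each. The epithelial genes CDS1 (2.06), LAMB3 (1.89) and ESRP1 (1.79, a call that 11 of the 18 settings ended) were higher, and APOL6 (-4.05), VIPR1 (-3.82), NNMT (-3.75) and ATP10A (-2.98) lower. The difference in TGFB2 (-1.24, adjusted p = 0.122) did not pass. In all 3001 genes, 14.1% of those tested, had an unadjusted p under 0.05, where a share of 0.05 does so with no change.

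**Figure D3:**
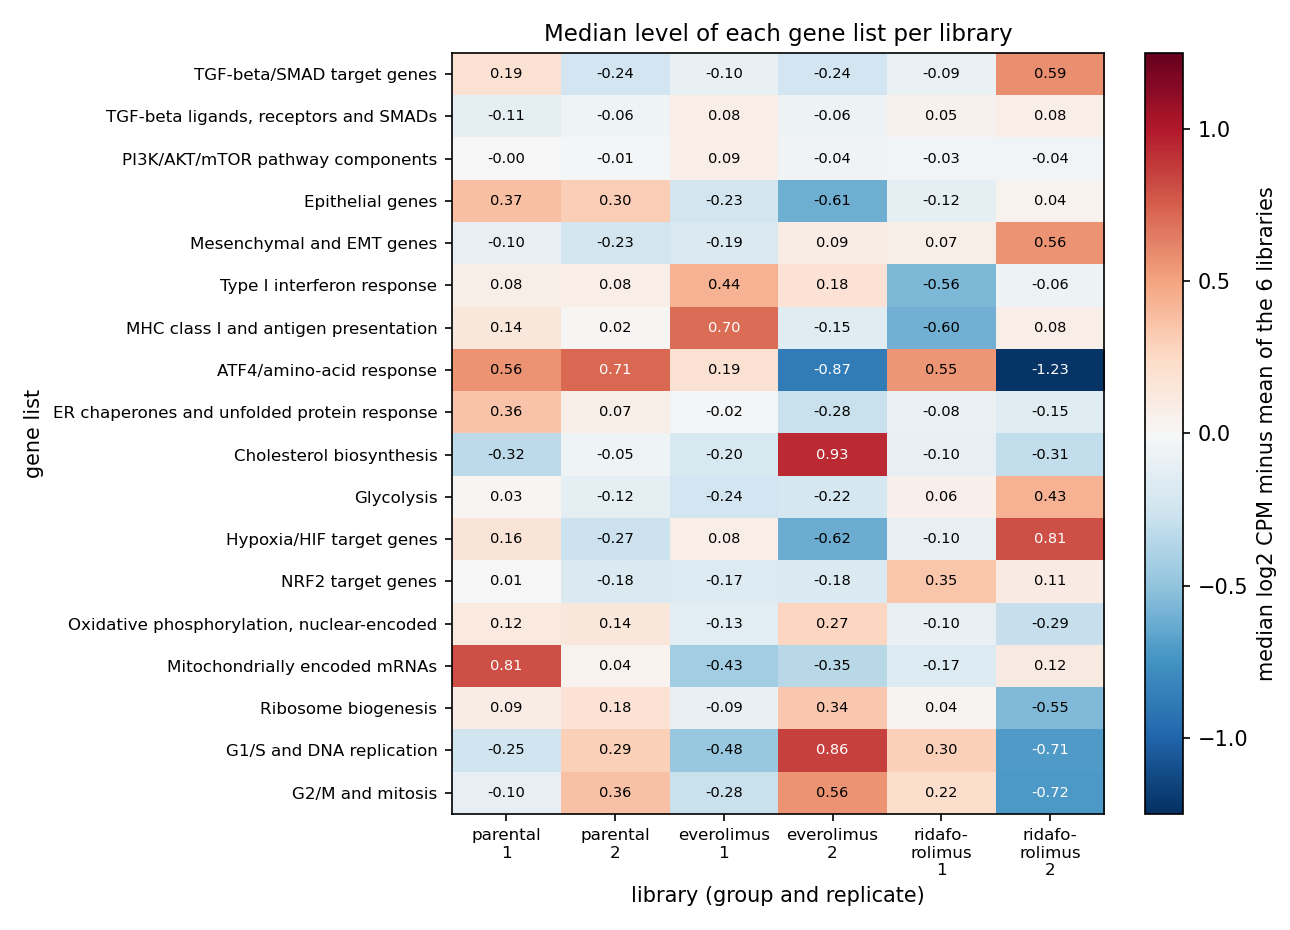
Level of 18 gene lists (rows) in the 6 libraries (columns), as the median over each list's genes of log2 CPM minus the gene's mean over the 6 libraries; red is higher and blue lower. The ATF4 list stands at 0.56 and 0.71 in the parental libraries, at 0.19 and -0.87 in the everolimus and at 0.55 and -1.23 in the ridaforolimus libraries.

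As groups, 7 lists were higher and 8 lower in the ridaforolimus than in the everolimus line, all with adjusted p = 0.890 with an estimated correlation. Interferon response genes had 31 of 33 members lower (median -0.62, adjusted p = 6.02e-06), 9 of which fell when adjusted over the list alone, OAS3 (-1.76), MX1 (-1.65) and IRF1 (-1.47) among them. Glycolysis had 22 of 23 higher (median 0.45, adjusted p = 1.29e-04), and PGK1, HK2 (1.04), HK1 (0.92) and ALDOC (1.95) rose when adjusted over the list alone. Cholesterol synthesis had 22 of 24 lower (median -0.67, adjusted p = 5.58e-04), with SQLE at -1.48 and 0 past the threshold over the list alone, and this call ended without everolimus replicate 2 (adjusted p = 0.939). DESeq2 called 657 genes and limma-voom 108. The edgeR count was 48 and 46 without parental replicate 1 and 2, 123 and 95 without everolimus replicate 1 and 2, and 84 and 19 without ridaforolimus replicate 1 and 2.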

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

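Every result here was singled out because the everolimus-resistant and ridaforolimus-resistant lines differed from each other in a direct test of that difference, with values given as ridaforolimus over everolimus on the log2 scale. The direct test was planned, while all tests of the chromosome X pattern were chosen after the result was seen.

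Genes of chromosome X made up a large part of the higher ones: EDA (3.99), HMGN5 (2.78), the glycolytic enzyme PGK1 (2.25), SH3BGRL (1.96), the cytoskeletal linker MSN (1.68) and the ribosomal protein RPS4X (1.36) all lie between 60 and 90 Mb. EDA2R, a receptor of the EDA-A2 ligand at 66595637 to 66639298 on chromosome X, had 0 counts in the parental and everolimus libraries and 3.96 and 2.12 CPM in the ridaforolimus libraries. It was at least 29.3-fold higher than in the everolimus line with a floor of 3 counts over the group. Its fitted value of 8.40 depends on the prior count, and DESeq2 did not call it (adjusted p = 0.555).

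Off chromosome X, the adhesion molecules LSAMP (4.0) and CNTN1 (2.74), the phosphodiesterase PDE2A (3.03), the calcium-binding CALB2 (2.72), the small heat-shock protein HSPB8 (2.71), the channel protein PANX2 (2.64), FBXL13 (2.46) and the matrix protein LTBP2 (2.40) were higher in the ridaforolimus line. So were the epithelial genes CDS1 (2.06), LAMB3 (1.89) and ESRP1 (1.79), CDYL2 (1.65), OSGIN1 (1.66), a target of NRF2, and PIK3CD (1.47). LCP1, a leukocyte marker by its list, was higher at 1.93, with 121 and 108 CPM against 22.7 and 37.5 CPM, while another member, ITGB2, stood at -1.32. GATA3, a luminal epithelial marker by its list, was lower (-2.38), at 0.915 and 0.95 CPM against 3.91 and 5.88 CPM. The luminal list itself had 5 members above 0 and 4 below (median 0.29, adjusted p = 0.608 by camera).

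Lower in the ridaforolimus line were APOL6 (-4.05), the peptide receptor VIPR1 (-3.82), NNMT (-3.75), ATP10A (-2.98), FST (-2.97), TIAM1 (-2.44), the matrix protein FBLN1 (-2.31), CASC19 (-2.29), PLIN4 (-2.09), MXRA8 (-1.49), the coagulation factor F3 (-1.47) and FKBP5 (-1.35). VIPR1 moved apart from parental cells in opposite ways, by 2.7 in the everolimus and -1.12 in the ridaforolimus line, with adjusted p = 0.205 and 0.262.

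Most other settings of the processing ended some of these calls: 15 of 18 for OSGIN1, 14 for FKBP5, 12 each for PIK3CD and MXRA8, 11 each for FST, ESRP1, LSAMP and PDE2A and 10 for FBLN1, and 13 of 17 for CASC19, 10 of 17 for GATA3, 9 of 17 for PGK1 and 10 of 16 for EDA2R.

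Of the lists, TGF-beta/SMAD targets (median 0.51, adjusted p = 0.0249), glycolysis (0.45), hypoxia targets (0.69, adjusted p = 0.00799), epithelial genes (0.31, adjusted p = 0.0191), matrix proteases (0.49, adjusted p = 0.00799), NRF2 targets (0.16, adjusted p = 0.00250) and the melanoma-type genes of MDA-MB lines (0.79, adjusted p = 0.0258) were higher, each with adjusted p = 0.890 with an estimated correlation. Cholesterol synthesis (-0.67), ribosome biogenesis (-0.30, adjusted p = 5.58e-04), G1/S genes (-0.46, adjusted p = 0.0191), G2/M genes (-0.37, adjusted p = 0.0108), interferon response (-0.62), the list of MHC class I and antigen presentation (-0.51, adjusted p = 4.17e-04), YAP/TAZ targets (-0.29, adjusted p = 0.0279) and oxidative phosphorylation (-0.29, adjusted p = 1.29e-04) were lower, again with adjusted p = 0.890 with an estimated correlation. Members past the threshold adjusted over the list alone were LTBP2 for SMAD targets, CDS1, LAMB3, ESRP1 and KRT19 (1.5) for epithelial genes, OSGIN1 for NRF2 targets, TYRP1 (2.67) for melanoma-type genes, F3 and TGFB2 (-1.24) for YAP/TAZ targets, TIMP4 (-1.90), which fell, for matrix proteases, and PSMB8 (-2.0), CIITA (-1.47) and HLA-DRA (-1.81) for antigen presentation. CIITA and HLA-DRA belong to class II presentation or its control.

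Of these lists, glycolysis and interferon response kept their calls without any 1 library. Without ridaforolimus replicate 2 the adjusted p was 0.562 for SMAD targets, 0.525 for hypoxia, 0.816 for ribosome biogenesis, 0.0936 for epithelial genes, 0.271 for matrix proteases, 0.236 for YAP/TAZ, 0.0668 for oxidative phosphorylation and 0.190 for melanoma-type genes. Without everolimus replicate 2 it was 0.105 for SMAD targets, 0.939 for cholesterol, 0.391 for hypoxia, ribosome biogenesis and melanoma-type genes, 0.223 for epithelial genes, 0.566 for YAP/TAZ and 0.434 for oxidative phosphorylation. Without everolimus replicate 1 it was 0.120 for SMAD targets and 0.105 for antigen presentation, and without ridaforolimus replicate 1 it was 0.0881 for antigen presentation and 0.0563 for NRF2 targets. The G1/S and G2/M lists turned to the other direction without either replicate 2 of the resistant lines. With the cell-cycle covariate, added after the data had been seen, the adjusted p was 0.187 for SMAD targets, 0.0503 for ribosome biogenesis, 0.853 for G1/S and 0.563 for G2/M genes, 0.0951 for epithelial genes, 0.297 for YAP/TAZ and 0.109 for melanoma-type genes, and with no filter on low counts it was 0.0607 for epithelial genes.

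The pattern weighed is on chromosome X, in genes at a mean of at least 5 CPM over the 6 libraries. Against parental cells, 100% of the 59 genes at 60 to 90 Mb were higher in the ridaforolimus line (median 1.37, bootstrap interval 1.19 to 1.54). From 90 Mb on, 88.8% of the 161 genes were lower (median -0.67, interval -0.72 to -0.59). Of 232 windows of 10 Mb, 16 lay beyond chance in this line, 5 on X and 11 on chromosomes 3, 7, 8 and 10, where the largest median was 0.67 (chromosome 3, 150 to 160 Mb); 5 in the everolimus line and 26 in the direct comparison did, 0 and 5 of them on X. The values argue against chance placement of unrelated changes. In 1000 random reassignments of fold changes to positions, which take neighbours as independent, the empirical p of the largest window was 0.001, the smallest they can give. The values also argue against 1 library alone, whose smaller shift was 1.21. Release of 1 silenced X copy beside 1 equal active copy would raise genes at most 2-fold and lower none. The distal genes were lower, which argues against release alone as the source of both shifts. The proximal lower bound of 1.19 lay above a 2-fold rise. But its bootstrap takes neighbouring genes as independent, and the copies of X in these cells were not measured. Release of proximal genes beside a separate distal loss therefore stays open. Neighbours that move together anywhere do so by less: off X the largest median over 59 neighbouring genes was 0.58 (interval 0.38 to 0.68) and over 161 it was 0.39 (0.34 to 0.45), both on chromosome 3. Circular shifts, run first, gave an empirical p of 0.298, but they carry the block along and decide nothing. Parental cells mixed into the ridaforolimus libraries stay open. At untreated levels CASC19 would allow at most 1.53% and CSF3 4.11% of them, but levels of such cells in the drug were not measured, and both genes had lower estimates in the everolimus line as well. Of the genes off X at 10 CPM or more in the parental and everolimus libraries, 0 held the share under 10%, and the lowest bound was 11.6% (APOL6). With a minimum of 3 CPM, set after these values were seen, 3 did: KIF21B (5.83%), GLB1L2 (7.68%) and SLC1A7 (9.39%), each at 0 to 2 counts per ridaforolimus library. These bounds hold only if such cells kept the levels of the parental and everolimus libraries. A mixture with cells of another kind was not tested. A gain of one and a loss of another segment of X in this line may account for shifts shared by 100% of these proximal genes. Such a shared shift alone would not account for the largest rises there, EDA (4.6) and HMGN5 (3.67), while HDX stood at 0.12. Nor would it account for EDA2R, which had 0 counts in the parental libraries and was at least 27.7-fold higher with the floor. No DNA was measured, the threshold of that test was set with the medians known, and whether the drug or culture alone selected such cells was not tested.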

How the results depend on the processing

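The cell-cycle covariate, the fit without chromosome X, the protein-coding fit and the split of the parental libraries were chosen after the data had been seen, and the other alternatives were planned. Counts are given for the everolimus, ridaforolimus and direct comparisons in this order. In edgeR 1, 68 and 158 genes passed, all of them at least 2-fold, with 5, 10 and 15 lists, 1 gene shared between the lines and PMEPA1 at 1.08 and 1.42. Of the alternative values of these results 125 stayed within the limits set, 121 moved and 4 passed a threshold that they had missed. The cause was not tested unless stated.

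With library size only, or with upper-quartile factors, 0 genes passed in the everolimus line, so 0 were shared, while ridaforolimus calls numbered 82 (54 higher, 28 lower) and 80 (54 higher, 26 lower) beside 68 (41 higher, 27 lower). DESeq2's size factors in edgeR gave 1, 70 and 144.

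With no filter on low counts 493, 1195 and 1362 genes passed (411, 961 and 1103 at least 2-fold), 163 were shared, and PMEPA1 passed in both lines (1.07, adjusted p = 0.00801, and 1.41, adjusted p = 2.0e-05). Unfiltered, edgeR's prior degrees of freedom went to infinity, and unchanged data simulated for the ridaforolimus comparison gave 49.0 false calls on average against 0.333 with the filter (3 rounds). In that simulation every gene removed by the filter was given the largest dispersion of the tested genes. The number of false calls in the real data may therefore differ. With at least 5 CPM in 2 libraries 0, 63 and 81 genes passed (81 at least 2-fold), 0 were shared, and 8 lists were called in the everolimus line. With protein-coding genes only, 0, 63 and 75 passed (75 at least 2-fold), with 8 lists in the everolimus line and 0 genes shared. Without chromosome X it was 1, 37 and 74. Calls on X numbered 0, 25 and 34, and 0, 6 and 50 calls off X ended as well (adjusted p at most 0.0701); the unaltered p-values adjusted over genes off X alone also gave 1, 37 and 74, so the adjustment accounts for these counts.

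Fits to only the 2 groups compared, with 2 residual degrees of freedom, gave 0, 127 and 0 genes (0, 127 and 0 at least 2-fold) and 0 shared. The replicate block gave 0, 28 and 49 genes (0, 28 and 49 at least 2-fold), 0 shared and PMEPA1 at 1.09 and 1.43; all 28 and 47 of the 49 were among the calls without it. The numbers do not pair the samples: differences between the replicates correlated at 0.329, -0.167 and -0.186 between the groups, and the labels give no shared day or batch. With the parental libraries split between the lines, 1 to each, 0 genes were shared both ways, and the correlation of the lines was 0.119 and 0.204 beside 0.383.

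DESeq2 called 150, 574 and 657 genes (139, 470 and 558 at least 2-fold), with 49 shared and PMEPA1 past the threshold in the ridaforolimus line (1.41, adjusted p = 0.00633). In the self-test it made about as many calls of 4-fold changes as edgeR with more false ones. Limma-voom gave 1, 72 and 108. The cell-cycle covariate, with 2 residual degrees of freedom, gave 95, 730 and 690 genes (89, 489 and 512 at least 2-fold), 50 shared, 8 lists in the direct comparison and PMEPA1 past the threshold in the ridaforolimus line (1.45, adjusted p = 0.0363). PMEPA1's adjusted p ranged from 0.00801 to 1.000 over the alternatives in the everolimus line and from 2.0e-05 to 0.610 in the ridaforolimus line. An adjusted p under 0.01 left 0, 1 and 0 genes (0, 1 and 0 at least 2-fold), and a test against 1.5-fold 0, 38 and 47. Where edgeR gave 0 in the everolimus line, 1866 genes (8.79% of those tested, part of them by chance) had an unadjusted p under 0.05 in the unaltered fit, and DESeq2 called 150.

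Leaving out 1 library gave 0 to 3, 1 to 276 and 19 to 123 genes (0 to 3, 1 to 274 and 19 to 123 at least 2-fold), 4 to 16, 7 to 13 and 6 to 20 lists, 0 to 2 shared genes, a correlation of the lines of 0.296 to 0.537, and PMEPA1 at 0.70 to 1.53 and 1.07 to 1.87. A group left with 1 library is assumed to vary like the others. Each call of a named gene kept its direction in all alternatives, with 881 values on the same side of the threshold and 359 not.

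Lists held under the prior count of 0.5 (5, 10 and 15), while an estimated correlation and fry gave 0 in each comparison. Of the alternative values of list calls 453 held and 110 lost significance. In 6 the direction turned, coded 1 for up and -1 for down: cholesterol synthesis in the everolimus line without everolimus replicate 2 (-1), G2/M genes in the ridaforolimus line without ridaforolimus replicate 2 (1), and G1/S and G2/M genes in the direct comparison without everolimus replicate 2 (1 each) or ridaforolimus replicate 2 (1 each). At 13134567 to 15556246 counts and 2 libraries per group, 2-fold changes were mostly missed in the self-test. In the real data some estimates beyond 4-fold did not pass either. A gene that did not pass may therefore still have changed by that much.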

Other observations

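Tests in this part were chosen after the result was seen, except the count of calls with the cell-cycle covariate, which was set before that fit was run, although the covariate itself was chosen after the data had been seen. Genes named in the next paragraph were chosen after their values were seen.

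Some genes were close to silent on one side only. The motor protein KIF21B and GLB1L2 had 0 counts in both ridaforolimus libraries and means of 8.32 and 3.70 CPM in parental cells, at least 74.3-fold and 33.1-fold lower with a floor of 3 counts over the group. On the other side NEXMIF (6.02 and 11.6 CPM) and POF1B (6.78 and 9.57 CPM), both on chromosome X, had at most 0.0764 CPM in any other library. TP63, a transcription factor of basal epithelium, rose from 0.764 and 0.282 CPM in parental to 16.8 and 16.1 CPM in ridaforolimus-resistant cells (4.97 ± 0.46, adjusted p = 0.0109) and stood at 0.362 and 0.595 CPM in the everolimus line. Toll-like receptor TLR4 was lower in the ridaforolimus than in the everolimus line (-2.0 ± 0.20, adjusted p = 0.0116), as was the hyaluronan synthase HAS2 (-3.33 ± 0.50, adjusted p = 0.0354, a call that 9 of 18 other settings ended), while neither passed against parental cells.

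Several other gene groups did not pass. Cytosolic ribosomal proteins had medians of 0.08 and 0.15 in the everolimus and ridaforolimus lines (adjusted p = 0.186 and 0.127), lysosomal genes 0.01 and -0.07 (0.943 and 0.452), autophagy genes -0.07 and 0.05 (0.363 and 0.748), p53 targets -0.14 and -0.11 (0.149 and 0.606) and mesenchymal genes 0.27 and 0.42 (0.482 and 0.101). Markers of other cell types were tested as lists too: luminal epithelium had adjusted p = 0.149 and 0.0937, leukocytes 0.805 and 0.595, endothelium 0.894 and 0.623 and the MDA-MB-231 reference set 0.805 and 0.149. Basal and fibroblast marker lists had fewer than 5 tested genes. RN7SL1, a small cytoplasmic RNA without a poly(A) tail, took 2.07% to 3.32% of the counts, and MALAT1 at most 0.0146%.

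The everolimus line gave few calls although its self-test recovered 75.6% of 4-fold changes among genes at a mean of at least 1 CPM. That test drew each gene on its own, without spread shared by a library's genes, and may overstate recovery in the real data. SPINT1, CSF3 and VIPR1, for example, had estimates beyond 4-fold in this line and did not pass. Spread within the groups along a cell-cycle axis is a candidate explanation of the few calls: with the median level of the G1/S list as a covariate 95 genes passed in place of 1. The covariate was built from the same libraries and leaves 2 residual degrees of freedom, and the other comparisons gained calls as well (730 and 690), so the gain is not particular to this line.

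Within each group the library higher in G1/S genes (parental 2, everolimus 2 and ridaforolimus 1) was also higher in G2/M genes (by 0.48, 0.79 and 0.89) and lower in hypoxia targets (-0.42, -0.69 and -0.88) and immediate-early genes (-0.76, -0.40 and -0.96). In 3 of 3 groups the G2/M and hypoxia differences lay beyond those of 10000 random lists of like expression. This count restates differences already seen, so it decides nothing about the growth state of the culture at harvest. Cholesterol synthesis was higher in the same libraries (0.23, 1.15 and 0.24; beyond 99.96%, 100% and 97.0% of the random lists), everolimus replicate 2 among them, without which the cholesterol call of that line turned. ATF4 targets did not follow the axis (0.08, -1.07 and 1.73), and density, medium and harvest day are not given in the labels.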
